A study of Homo sapiens with 18 samples.

How the data were processed

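RNA was sequenced from A375 cells, an established human melanoma line, which per the labels came from ATCC and was grown in DMEM with fetal bovine serum. The labels define 6 groups of 3 libraries. Control cells carried a guide RNA against GFP, a sequence foreign to the cells. A further group carried the same guide and overexpressed SOX10. TADA2B, which encodes a subunit of the SAGA histone acetyltransferase and deubiquitinase complex, was knocked out with 2 different guides, and each knockout line was profiled with and without SOX10 overexpression. Per the labels' protocols, total RNA was purified on spin columns and libraries were made with the KAPA Stranded mRNA-Seq kit, which selects polyadenylated RNA.

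The authors deposited 1 table of raw read counts per gene, with no normalization. Per the submitters' processing notes, HISAT2 and HTSeq were used with genome build hg38. Their versions, the annotation and the strand setting of the counting are not given in the sources used here. Reads of a gene and of an antisense or overlapping gene could therefore not be told apart, and genes with near-identical relatives, such as the TRIM48 family and the HLA genes, carry some uncertainty in how reads were assigned. The table held 58721 Ensembl gene identifiers, of which 58721 were genes of GENCODE 29 and 58252 had a symbol in the gene name table used. A further check found 45 identifiers for the pseudoautosomal region of Y. In all, 17004 identifiers had a count of 0 in every library. Symbols, biotypes and hg38 coordinates were taken from these annotations by identifier. All 18 columns of the table matched the title of 1 sample each.

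Total counts ran from 58573910 to 79874237 per library. A count of 3 corresponded to a counts-per-million (CPM) value of 0.0376 to 0.0512 depending on the library, and such floors cover counting error only. Levels are given as mean CPM with the standard deviation (SD) over the 3 libraries of a group, using effective library sizes. Each library was compared with the others of its group before averaging. Pearson correlations of log CPM between libraries of a group were 0.998 to 0.999 across genes, which are not independent replicates. The chi-square per degree of freedom between them was 3.54 to 11.8 over genes with a pair count of at least 20, so no pair of libraries looked like 1 library counted again. The labels number the libraries of a group 1 to 3 and do not say whether they came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. The 2 guides are the independent perturbations.

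Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as factor, which left 21060 genes. Library sizes were adjusted with TMM factors, and 1 negative binomial model with 6 group means was fitted to all 18 libraries by robust quasi-likelihood, with 12 residual degrees of freedom. The common biological coefficient of variation was 4.02%. Every contrast was tested with edgeR's two-sided quasi-likelihood F test and Benjamini-Hochberg adjustment over the genes tested, and a gene was called changed at an adjusted p under 0.05. Counts of genes changed at least 2-fold also required an absolute log2 fold change of at least 1. The contrasts were knockout against control for each guide and for their mean, SOX10 overexpression in control cells, in each knockout line and in their mean, knockout with SOX10 against control, knockout against control within SOX10-overexpressing cells, the difference of the SOX10 effect between knockout and control cells (the interaction), and guide 2 against guide 1. All adjusted p-values of genes come from this test, and fold changes are the fitted ones with their standard error (SE).

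The extent to which SOX10 turned back the knockout profile was measured across guides, so that no library entered both sides. Genes were chosen by 1 guide against control, and the SOX10 effect was read in the other guide. Intervals of these shares are 95% exact binomial (Clopper-Pearson) intervals over genes and cover counting only, since genes are not independent. Because both guides were compared with the same control libraries, 20 simulations of unchanged groups against those controls were run, for the lines without SOX10 and again for the lines with it, to give the overlap expected without any effect.

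In all, 31 gene lists were fixed before the data were examined, covering chromatin complexes, melanoma states, signalling outputs, immune programs, proliferation, metabolism, RNA quality and markers of other cell types. Each was tested with camera in limma 3.58.1 on log CPM (prior count 2) with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. Their p-values were adjusted over the lists of a comparison. Members were also counted with p-values adjusted over the list alone. The designs, the gene lists, the alternatives and the rule for naming genes were all set before the data were examined, except where stated. TADA2B and SOX10 are always named. For the 4 main contrasts, the named genes are the 6 with the largest rise and the 6 with the largest fall among changed protein-coding genes with a mean of at least 5 CPM in the higher arm, with all libraries of one arm above all of the other, and for a mean of guides with both guides past the threshold. For the interaction and for guide 2 against guide 1 the 4 largest each way were taken, the interaction with both guides past the threshold in place of the rule on libraries. From a gene list, up to 4 members with the lowest adjusted p are named. SAGA subunits may be named anywhere. Not every gene this rule takes is given in the text.

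The model was tested on simulated data. Counts were drawn for the real genes, with the library sizes and dispersions of these libraries, and with 200 of them changed by known folds. The 200 were taken from genes above 1 CPM in control cells, so recovery at lower levels was not simulated. For knockout against control, on 19449 genes, 94% of genes changed 1.5-fold and 100% of genes changed 2-fold were recovered with 19 false calls. For the interaction, on 19427 genes, 76% and 96% were recovered with 7 false calls. Among 31 simulated lists of 30 genes, the list raised 1.5-fold was found and 0 of the other lists were called. Members of these lists were also above 1 CPM and were drawn independently. The list simulation therefore does not cover correlation between genes.

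The alternatives were RLE size factors, no low-count filter, a filter at a mean CPM of 1, the replicate number as a block, each library left out in turn, only the compared groups in the fit, DESeq2 1.42.0 with its Wald test, and limma-voom. Scaling by library size without TMM was added after the TMM factors were seen to differ between knockout and control libraries. Mean TMM factors were 0.932 in control cells and 0.934 with SOX10, against 1.03 and 1.02 with guide 1 without and with SOX10 and 1.04 in both groups of guide 2. The guide sites in the genome were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.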

Results

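Expression was profiled in A375 melanoma cells that per the labels carried a knockout of TADA2B or a control guide, TADA2B being a subunit of the SAGA chromatin complex, with and without overexpression of SOX10, a transcription factor of the neural crest and melanocyte lineage. The design addresses how knockout of TADA2B changed the transcriptome and how far SOX10 acted on the knockout profile. There were 6 groups of 3 libraries: control, control with SOX10, and each of 2 knockout guides without and with SOX10. Mean depth was 71.4 M counts in control cells, 77.0 M with SOX10, 72.3 and 74.5 M in guide 1 without and with SOX10, and 74.9 and 69.2 M in guide 2 without and with SOX10. In a principal component analysis of log CPM, component 1 held 50% of the variance and component 2 held 24%. On these 2 components the libraries of each group lay close together. Component 4, with 2.27% of the variance, set guide 2 replicate 2 apart, at −26.4 against −4.28 and −8.17 for its group. Its chi-square per degree of freedom was 11.8 and 10.4 against these 2 libraries, and 4.6 between them. Mitochondrially encoded transcripts, a sign of RNA and cell state, took 0.732% to 1.46% of the counts. Their mean share was 0.831% in control cells and 0.895% in control cells with SOX10, and it was higher in all knockout groups, from 1.09% in guide 1 with SOX10 to 1.32% in guide 2 with SOX10. The 10 highest genes took 4.29% of the counts in control cells and 3.63% and 3.59% in the knockout lines.

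The TADA2B transcript was detected in every library and, with TMM scaling, was modestly lower in both knockout lines. TADA2B (ENSG00000173011; hg38 chromosome 4, 7041899 to 7057952) stood at 32.5 ± 0.315 CPM in control cells (SD, n = 3). It was 26.0 ± 0.403 CPM with guide 1 and 28.8 ± 1.36 CPM with guide 2, and averaged over guides it fell by 0.25 on the log2 scale (SE 0.040, adjusted p = 1.16e-06). Its raw counts per library were 1865 to 2513 with guide 2 and 2116 to 2201 in control cells. Library-size scaling in place of TMM moved the median log2 change of all genes up by 0.147 with guide 1 and 0.162 with guide 2. Part of the TADA2B fall, above all with guide 2, therefore rests on the scaling. With SOX10 the TADA2B level was 31.0 ± 0.578 CPM in control cells, 25.3 ± 1.45 CPM in guide 1 and 26.9 ± 1.07 CPM in guide 2. Neither SOX10 contrast passed the threshold, with adjusted p-values of 0.289 in control cells and 0.0799 in knockout cells, although the TADA2B value in knockout cells passed in 5 alternatives, among them RLE scaling (adjusted p = 0.0476) and DESeq2 (0.0408). A guide introduces small insertions or deletions and need not lower the transcript, so the count does not measure loss of the protein.

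SOX10 itself was lower in both knockout lines and only partly refilled by the overexpression. SOX10 (ENSG00000100146; chromosome 22, 37970686 to 37987422) was at 354 ± 12.2 CPM in control cells, 83.6 ± 3.02 CPM with guide 1 and 43.4 ± 3.16 CPM with guide 2 (SD, n = 3). Its log2 change was −2.08 (SE 0.039) with guide 1 and −3.03 (SE 0.041) with guide 2, and the adjusted p for the mean of both was 1.23e-34. Overexpression brought the SOX10 count to 452 ± 1.57 CPM in control cells, 291 ± 13.9 CPM in guide 1 and 246 ± 5.44 CPM in guide 2. The rise was 1.28-fold in control cells (adjusted p = 1.42e-09) and 4.45-fold in knockout cells (adjusted p = 4.37e-34), and the knockout lines with SOX10 stayed below control, with a log2 change of −0.40 (adjusted p = 7.37e-13). Reads of a transgene lacking the untranslated regions, or one with altered codons, would not all be counted at this gene, and the construct is not described in the sources used here.

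**Figure D1:**
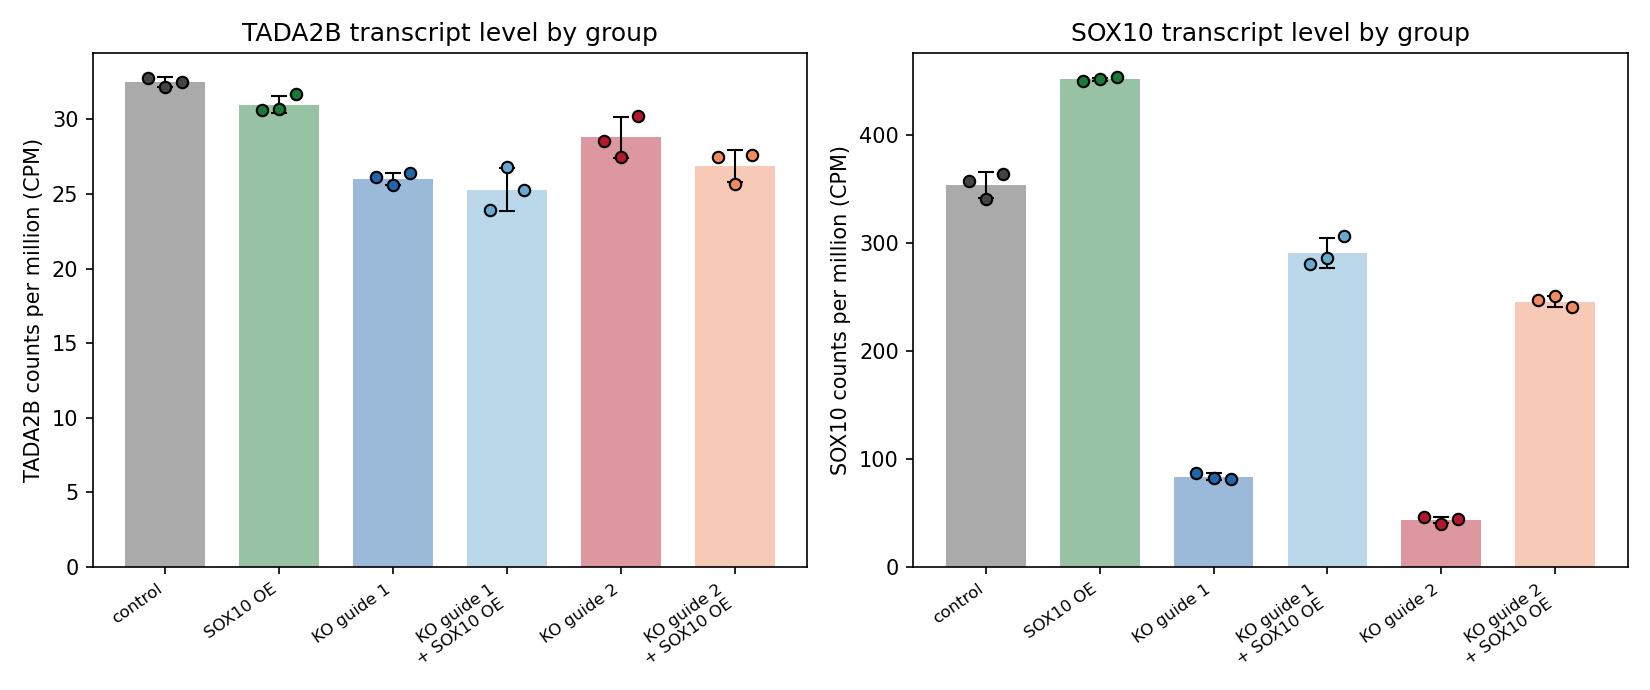
Level of TADA2B and of SOX10 in CPM on linear axes starting at 0, in the 6 groups. Bars are means, whiskers are the SD and points are the 3 libraries of each group; SOX10 stood at 354 CPM in control cells and at 83.6 and 43.4 CPM in the knockout lines, against 32.5, 26.0 and 28.8 CPM for TADA2B.

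Knockout of TADA2B raised the urokinase gene PLAU and the lipoprotein receptor gene OLR1 from low levels and lowered the retinoid receptor gene RXRG and the matrix gene ITIH5 to low levels. PLAU, a secreted protease, rose 81.7-fold from 0.116 ± 0.0751 CPM in control cells to 8.23 ± 0.283 CPM with guide 1 and 11.1 ± 0.713 CPM with guide 2 (SD, n = 3, adjusted p = 4.59e-29), and OLR1, a receptor for oxidized lipoprotein, rose 95.6-fold. The calcium-activated chloride channel gene ANO2 rose 171-fold, the receptor tyrosine kinase gene ROS1 rose 54.5-fold, and the meiotic gene SHOC1 rose from 0.0552 to 4.44 and 5.76 CPM. Among the genes that fell, the homeobox gene PKNOX2 was 71.7-fold lower, ITIH5 57.7-fold, RXRG 45.4-fold, the atypical cadherin gene FAT3 39.6-fold, the collagenase gene MMP8 36.2-fold and the receptor phosphatase gene PTPRZ1 31.1-fold. All of these had adjusted p-values of 5.65e-23 or less and had every library of each guide on the same side of every control library, as the rule for naming them asks. The control totals of the genes named as rising were only 8 to 23 counts, so their folds are less certain than their direction.

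A total of 12230 of 21060 genes changed on average over the guides, 6025 of them higher and 6205 lower. At least 2-fold changes numbered 2015 upward and 1134 downward. Scaling by library size in place of TMM, chosen after seeing the data, moved the median log2 change of all genes up by 0.155 and gave 9112 higher and 3545 lower genes, or 72% higher against 49.3%. Small changes shared by many genes therefore hold only relative to that shift, while 9570 of the genes kept their call and sign under both scalings.

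**Figure D2:**
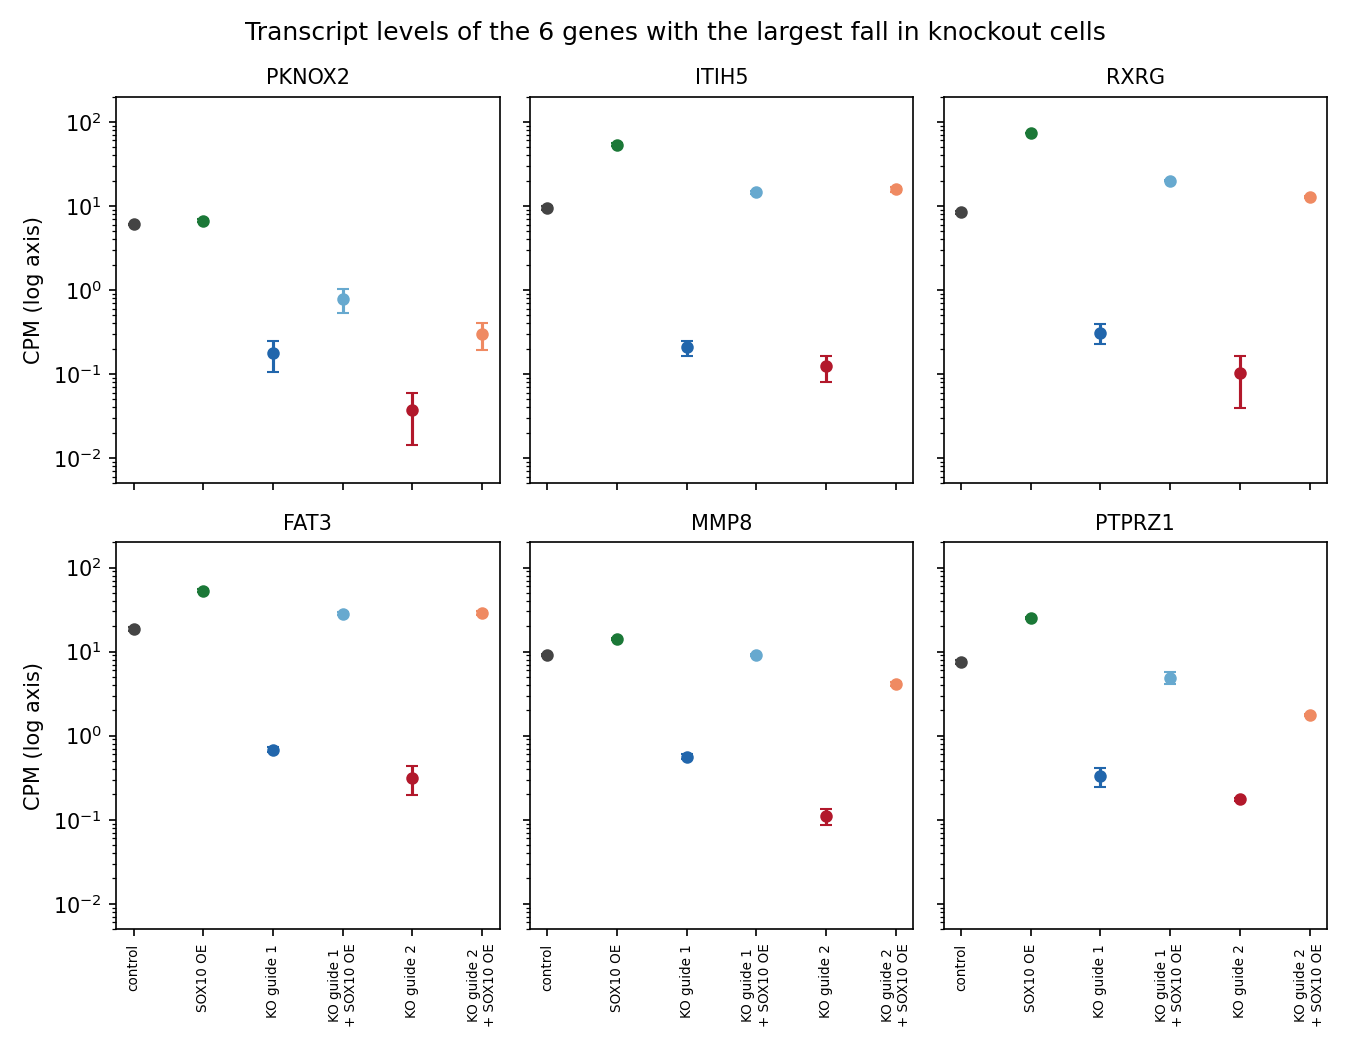
Mean CPM with SD (whiskers, clipped at the axis bottom) of the 6 genes with the largest fall in knockout cells, in the 6 groups, on a log axis; n = 3 libraries per group. RXRG stood at 8.37 CPM in control cells and at 0.309 and 0.102 CPM in the knockout lines, and at 19.8 and 12.7 CPM in the knockout lines with SOX10.

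Genes of the SOX10 and Schwann or neural crest lineage fell together in the knockout. Of 29 members tested, 23 fell, 3 rose and 3 did not pass, and with library-size scaling 21 fell and 4 rose. The neuregulin receptor gene ERBB3 had a log2 change of −4.11, the cadherin gene CDH19 −3.35 and the transcription factor gene POU3F2 −3.17. The camera test of this list gave an adjusted p of 7.61e-09, and 0.00213 with an estimated correlation. Pigmentation and melanocyte genes moved apart, with 8 of 21 higher and 9 lower (adjusted p = 0.95). MITF, the master regulator of melanocytes, rose by a log2 of 1.15, and ACP5 and RAB27A rose by 1.63 and 1.00, whereas the melanin enzyme gene DCT had a change of −3.89. Of 30 genes of the undifferentiated, AXL-high melanoma state, 19 rose and 11 fell, and the list did not pass (adjusted p = 0.0848): TGFBI (1.48) rose, while SPARC (−1.04) and CDH2 (−0.99) fell. In these 3 lists 26, 17 and 30 members changed when adjusted over the list alone.

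Interferon-stimulated genes rose, and more antigen presentation genes fell than rose. Of 37 interferon genes, 33 rose and 2 fell, among them OASL (log2 change 4.65), ISG15 (3.17), GBP1 (1.78) and HERC5 (1.53). Their adjusted p was 2.96e-11, which became adjusted p = 0.082 with an estimated correlation. In antigen presentation, 14 of 25 genes fell and 8 rose, with the class II genes HLA-DRA (−2.67) and CD74 (−2.44) and their activator CIITA (−3.42) lower, at an adjusted p of 0.0024 and adjusted p = 0.155 with an estimated correlation. Of 22 NF-kB and inflammatory cytokine genes, 15 rose and 4 fell: IL11 (2.66), TNFAIP3 (2.21) and TNFAIP2 (1.56) rose and CXCL1 (−2.82) fell. This list had an adjusted p of 0.00897, and 0.0464 with an estimated correlation, and it did not pass with library-size scaling (0.0635). The interferon, antigen presentation and NF-kB lists had 36, 22 and 20 changed members adjusted over the list alone. HLA genes are near-identical relatives, and their counts carry that uncertainty.

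Outputs of MAPK signalling fell and the receptor kinase genes split. Of 25 MAPK output genes, 16 fell and 7 rose: the cyclin gene CCND1 (−1.51), the feedback inhibitor gene SPRY2 (−1.75), ETV5 (−1.15) and TRIB2 (−1.64) were lower, with an adjusted p of 0.00148 and 0.0464 with an estimated correlation. Of 22 receptor tyrosine kinase genes, 15 fell and 6 rose, with ERBB3 and NGFR (−1.80) lower and EGFR (1.34) and MET (0.74) higher. Its adjusted p of 0.0396 became adjusted p = 0.276 with an estimated correlation, and it did not pass with a filter at a mean CPM of 1 (0.0663), with only the compared groups in the fit (0.0588), or without control replicate 1, 2 or 3, guide 1 replicate 2 or 3, or guide 2 replicate 1 or 2 (0.0541 to 0.0797). YAP and TEAD targets rose in 14 of 24 cases and fell in 7, or 17 and 4 with library-size scaling, F3 (2.04) and CCN1 (1.70) rising and IGFBP3 (−1.02) and MYOF (−0.59) falling; the adjusted p was 0.0141, and adjusted p = 0.344 with an estimated correlation. The AP-1 and TGF-beta lists did not pass, with adjusted p-values of 0.2 and 0.972 and 6 and 12 members higher against 10 and 11 lower, or 8 and 13 against 9 and 8 with library-size scaling. NR4A1 (−2.27) and EGR3 (−2.41) fell in the former, and TNC (−1.62) fell and TGFBI (1.48) rose in the latter. From the MAPK to the TGF-beta list, 23, 21, 22, 16 and 23 members changed adjusted over the list alone.

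Proliferation genes were lower with TMM scaling, and part of this rested on the scaling. Of 26 genes of the G2 and M phases, 21 fell and 0 rose, against 15 lower and 7 higher with library-size scaling, with 2 members called in opposite directions by the scalings. KIF20A (−0.64), KIF11 (−0.62), CENPF (−0.52) and PLK1 (−0.45) had the lowest p-values, and the adjusted p was 1.02e-06, with 0.00606 at an estimated correlation. Of 26 S phase genes 22 fell and 2 rose, or 19 and 3 with library-size scaling, with MCM3 at −0.60 and TYMS at −0.69, and the adjusted p of 1.02e-06 became adjusted p = 0.155 with an estimated correlation. MYC targets fell in 20 of 30 cases and rose in 3, but in 9 and 9 with library-size scaling, which ended the call (adjusted p = 0.0024 against 0.153, and adjusted p = 0.313 with an estimated correlation). Genes of hypoxia and glycolysis fell in 17 of 25 cases and rose in 7 (LDHA −0.58, HK2 −0.71; adjusted p = 0.00465, and adjusted p = 0.159 with an estimated correlation). Of 22 p53 targets, 13 rose and 2 fell, with GDF15 at 3.10, FAS at 0.69 and CDKN1A at 0.36, and 20 rose with library-size scaling. Their adjusted p was 0.00409, and adjusted p = 0.0783 with an estimated correlation. Changed members adjusted over the list alone numbered 21, 24, 23, 24 and 15 in the order given.

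Matrix and adhesion genes moved both ways, and markers of epithelial cells and fibroblasts were higher. Of 34 matrix genes 14 rose and 18 fell, with TIMP3 (−3.61), LAMA4 (−1.98) and TNC (−1.62) lower; the median log2 change was −0.30, the mean was 0.04, and the list did not pass (adjusted p = 0.175). Of 26 integrin and adhesion genes 16 fell and 9 rose, or 13 and 9 with library-size scaling, with ITGB8 (−2.35), CADM1 (−1.57) and ITGA6 (−1.17) lower (adjusted p = 0.00897, and adjusted p = 0.109 with an estimated correlation). Of 11 keratinocyte or epithelial markers 8 rose and 1 fell: KRT8 (2.68), DSP (1.75) and SFN (4.42) were higher and KRT14 (−3.03) lower (adjusted p = 0.00187, and 0.0464 with an estimated correlation). Of 10 fibroblast markers 8 rose and 1 fell, and 9 rose with library-size scaling, with an adjusted p of 0.000213 and 0.0464 with an estimated correlation. LUM went from 2.61 ± 0.424 CPM in control cells to 21.9 ± 1.12 and 23.3 ± 1.74 CPM in the knockout lines, and MFAP5 (5.26), POSTN (4.10) and COL1A1 (3.12) rose with it. Leukocyte markers did not pass as a list (4 of 9 rose and 2 fell, or 4 and 1 with library-size scaling; adjusted p = 0.196). Of the signs of RNA quality, 4 of 13 mitochondrially encoded transcripts were higher, or 9 with library-size scaling, MT-CO2 by 0.54, and 6 of 12 replication-dependent histone transcripts were higher, H1-2 by 1.55, with adjusted p-values of 0.0808 and 0.0848 for the lists. Adjusted over the list alone, 32, 25, 9, 9, 6, 3 and 6 members of these lists changed.

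SAGA subunits moved both ways in the knockout. Of 24 subunits, TADA2B among them, 12 rose and 7 fell, and 15 rose and 3 fell with library-size scaling. USP22, the deubiquitinase of the complex, went from 374 to 277 CPM and SF3B3 from 712 to 576 CPM, while TADA3 went from 52.3 to 68.8 CPM. No subunit changed 2-fold, and the list did not pass (adjusted p = 0.406, 19 changed when adjusted over the list alone).

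**Figure D3:**
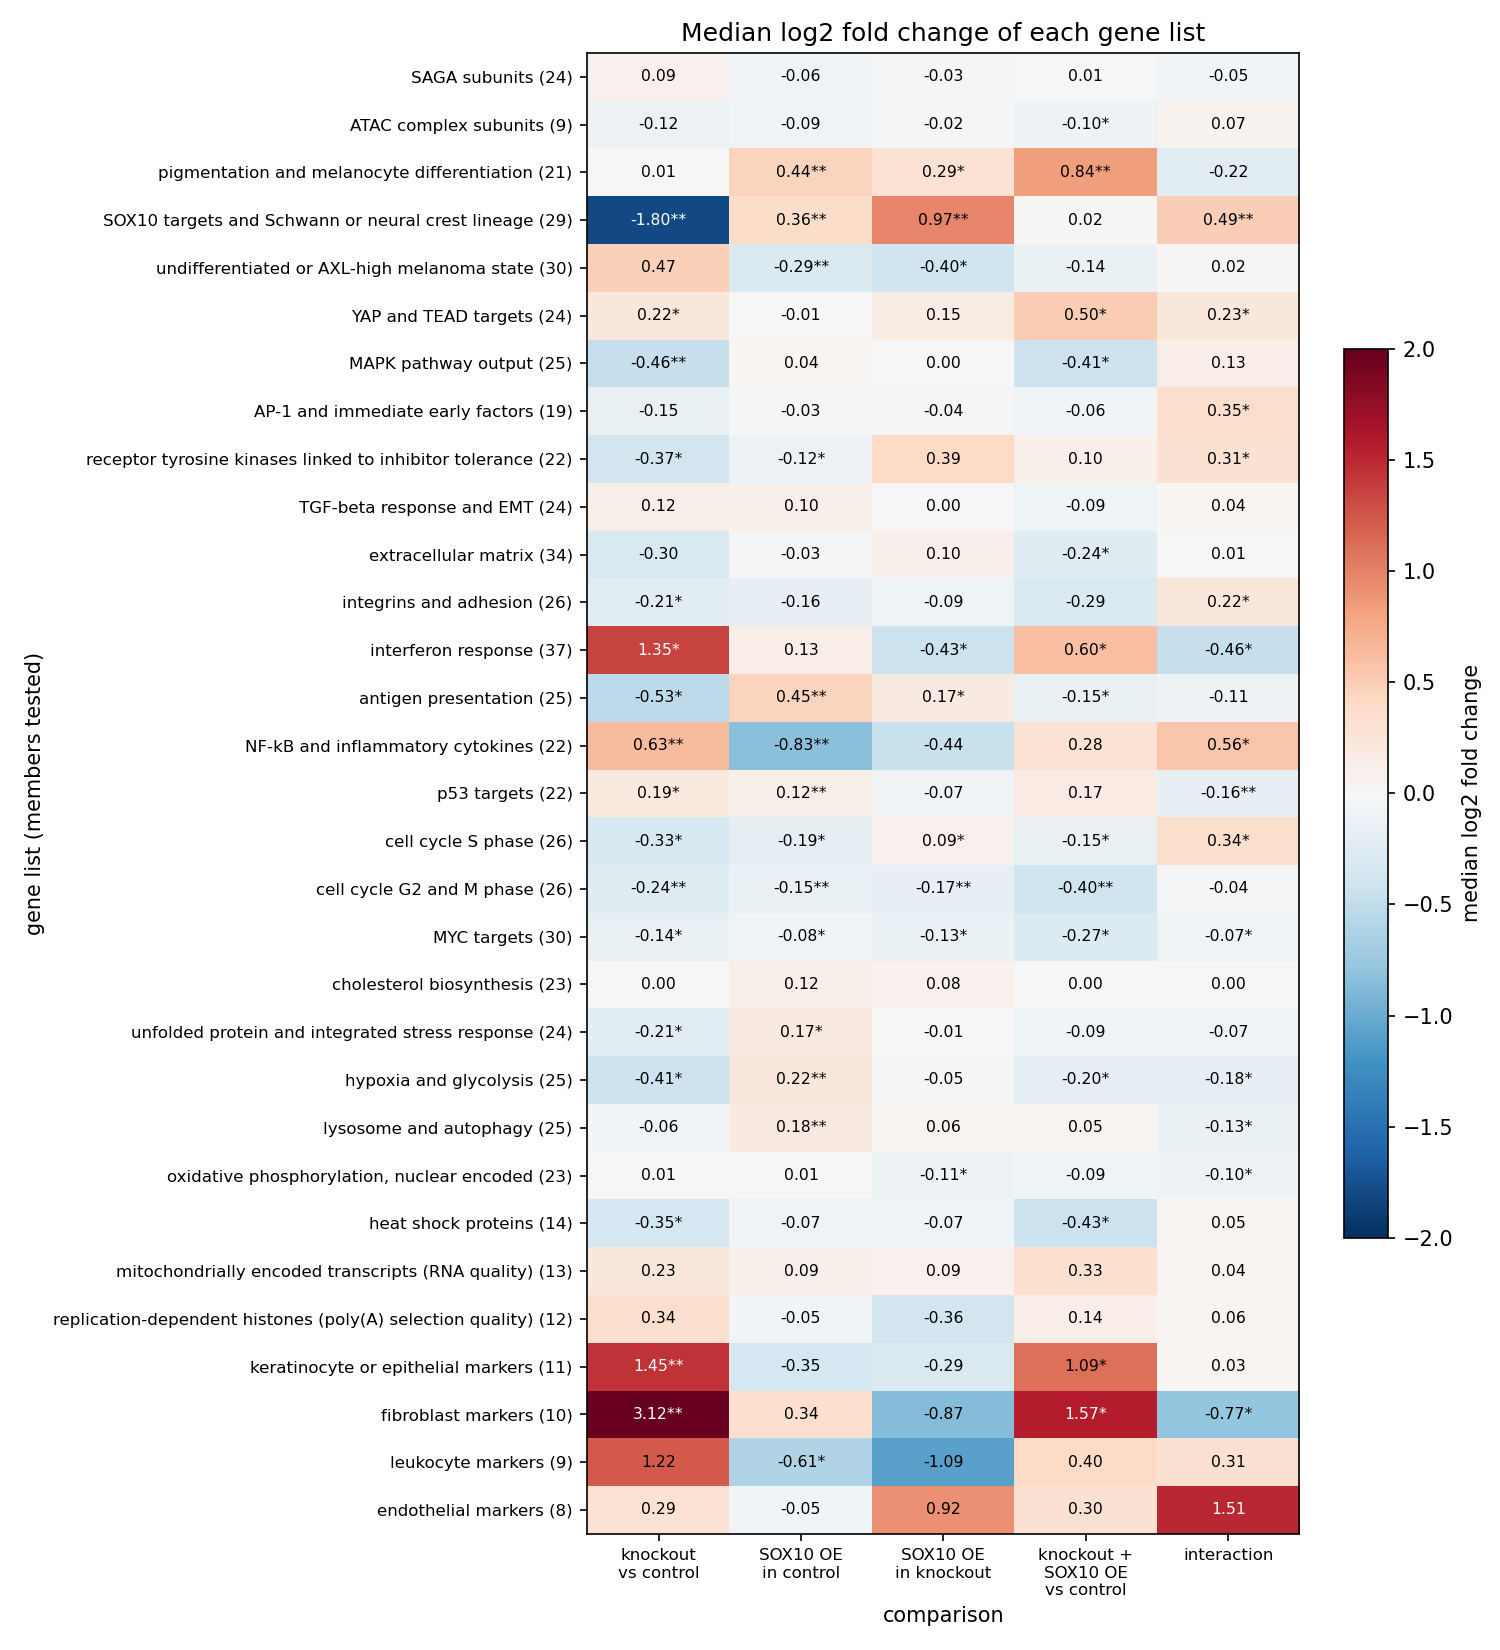
Median log2 fold change of the members of 31 gene lists (vertical axis) in 5 comparisons (horizontal axis), with colours stopping at −2 and 2. A single star marks an adjusted camera p under 0.05 at the preset correlation and a double star one that also holds with an estimated correlation; the knockout column shows SOX10 lineage genes lower, with a median of −1.80, and interferon genes higher, with a median of 1.35, and library-size scaling moves the median of all genes in that comparison up by 0.155.

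The 2 guides changed largely the same genes. Against control, guide 1 changed 11086 genes (5518 higher, 5568 lower) and guide 2 changed 11775 (5867 higher, 5908 lower), or 8382 and 3103, and 8874 and 3478, with library-size scaling. In both, 5007 genes were higher and 4990 lower, and 10 changed in opposite directions. Independent lists of these sizes would share 1537 and 1562. Changes of at least 2-fold with both guides numbered 1753 upward and 827 downward. Log2 changes correlated at r = 0.942 across genes, which are not independent replicates, with a covariance of 1.09. Simulated unchanged groups measured against the same controls gave r = 0.493, a covariance of 0.0213 and a mean of 0.25 genes called the same way. These values argue against the spread between the 3 shared control libraries as the source of the shared calls and of the covariance. The control libraries were not split between the guides. The simulations drew on that spread alone, so a difference of the control cells themselves, common to both comparisons, stays open.

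Guide 2 had the deeper loss of SOX10 and of its lineage genes. Of 1841 genes that differed between the guides, 1282 were lower and 559 higher with guide 2, and 123 and 9 by at least 2-fold. Library-size scaling gave 1116 and 815, so 42.2% rather than 30.4% were higher. SHISA2 was 4.49-fold lower with guide 2, at 3.50 against 15.8 CPM, the growth arrest gene GAS7 was 3.25-fold lower, MGAM2 3.13-fold and TNFRSF19 3.11-fold. The annexin gene ANXA3 was 2.09-fold higher and ANKRD1, a YAP target, 1.61-fold higher, as were ADAMTS6 (1.60-fold) and the keratin-associated KRTAP2-3 (1.58-fold). SOX10 lineage genes were lower with guide 2 in 15 of 29 cases and higher in 0, with ERBB3 at −1.15 on the log2 scale (adjusted p = 9.69e-17, and 8.66e-05 with an estimated correlation). Antigen presentation was lower in 15 of 25 genes, with HLA-DRA at −1.12 and CIITA at −1.45 (8.82e-23, and 0.000503 with an estimated correlation). MAPK outputs were lower in 14 of 25, with DUSP4 at −0.55 and CCND1 at −0.47, and higher in 2 (2.26e-09, and 0.00075 with an estimated correlation). Integrins were lower in 14 of 26 and higher in 1, with ITGB8 at −1.01 (2.49e-12, and 0.000503 with an estimated correlation). These lists had 16, 19, 18 and 19 differing members adjusted over the list alone. TADA2B was at 28.8 CPM with guide 2 and 26.0 CPM with guide 1 (adjusted p = 0.0438).

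Overexpression of SOX10 in control cells raised TRIM48, the myelin genes PMP2 and MOBP, and the melanin enzyme gene DCT from low or near-zero levels. TRIM48 went from 0.0551 ± 0.0601 to 69.7 ± 1.81 CPM, PMP2, a myelin protein of peripheral nerve, from 0.0903 ± 0.0267 to 40.4 ± 3.69 CPM, and the myelin gene MOBP from 0.00494 CPM, a single count, to 6.36 ± 0.728 CPM (SD, n = 3). The transporter gene SLC5A4 went from 3 counts to 10.2 CPM, the contactin gene CNTN6 from 0.0253 to 6.46 CPM, and DCT rose 153-fold, from 1.01 to 156 CPM. IL1RL1, the receptor of interleukin 33, fell 32.4-fold from 27.7 to 0.853 CPM. The carboxypeptidase gene CPA4 went from 84.0 to 8.89 CPM, and LYPD3, the hormone gene STC1, the complement gene C3 and SMOC1 were 7.73-fold, 7.71-fold, 7.42-fold and 6.80-fold lower. The adjusted p-values of these 12 genes were 3.53e-24 or less. TRIM48 belongs to a family of near-identical copies, so its reads may be shared with relatives. In all, 7245 genes changed, 3633 higher and 3612 lower, with 771 and 589 by at least 2-fold.

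Pigmentation, SOX10 lineage, antigen presentation and lysosome genes rose with SOX10 in control cells, and inflammatory and undifferentiated-state genes fell. Of 21 pigmentation genes 10 rose and 2 fell, with GPNMB at 1.74 and GPM6B at 2.49, and MITF going from 39.7 ± 0.54 CPM to a level 2.15-fold higher (adjusted p = 0.000163, and 0.0106 with an estimated correlation). Of 29 SOX10 lineage genes 17 rose and 6 fell, with RXRG at 3.15, PMP22 at 0.97 and L1CAM at −1.52 (0.000333, and 0.0182 with an estimated correlation). Antigen presentation rose in 19 of 25 genes and fell in 0, with CIITA at 0.86 and HLA-DRA at 0.57 (2.17e-10, and 0.0106 with an estimated correlation). Lysosome genes rose in 16 of 25 and fell in 3, and hypoxia genes rose in 14 of 25 and fell in 2, with the hypoxia gene BNIP3 at 0.62 (7.9e-05 and 2.21e-05, and 0.0266 and 0.0346 with an estimated correlation). In the other direction, 20 of 30 undifferentiated-state genes fell and 8 rose, with F2RL1 at −2.11 and COL5A1 at −1.05 (7.47e-05, and 0.0266 with an estimated correlation), and 13 of 22 NF-kB genes fell and 4 rose, with IL11 at −1.59 and CXCL1 at −1.87 (5.22e-05, and 0.0104 with an estimated correlation). S phase genes fell in 21 of 26 cases and rose in 0 (UHRF1 −0.56; 4.91e-08, and adjusted p = 0.102 with an estimated correlation), and G2 and M genes fell in 19 and rose in 1 (CCNB1 −0.26; 7.67e-05, and 0.0141 with an estimated correlation). In the order given, 13, 23, 19, 22, 18, 29, 19, 21 and 20 members changed adjusted over the list alone. KAT2B, an acetyltransferase subunit of SAGA, rose 4.56-fold from 38.3 ± 1.09 CPM, and 2 of the 24 SAGA subunits rose and 8 fell (list adjusted p = 0.3).

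PMP2, MOBP and TRIM48 also rose with SOX10 in knockout cells, and the matrix metalloprotease genes MMP1 and MMP3, which the knockout had raised, fell. PMP2 went from 0.0125 and 0.0387 CPM in guides 1 and 2 to 61.7 ± 2.48 and 83.9 ± 7.09 CPM. The monoamine transporter gene SLC18A1 went from 5 counts in guide 1 and 0 counts in guide 2, where 0 counts allow up to 0.0461 CPM in the shallowest library for counting error alone, to 21.2 ± 1.08 and 20.9 ± 0.941 CPM. The mucin gene MUC7 went from 1 count in each line to 9.17 and 11.5 CPM, MOBP from 2 counts in each line to 12.0 and 15.4 CPM, TRIM48 from 0.0134 and 0.0366 to 28.0 and 7.00 CPM, and the collagen gene COL14A1 from 0.0181 and 0.0289 to 7.84 and 7.07 CPM. Downward, the annexin gene ANXA10 fell 36.2-fold, the cadherin gene CDH11 24.5-fold and the neuronal membrane gene BASP1 20.4-fold. IL1RL1 went from 31.0 and 23.3 to 1.13 and 1.25 CPM, the collagenase gene MMP1 from 36.7 and 35.6 to 2.01 and 1.39 CPM, and MMP3, a stromelysin, fell 17.2-fold. The adjusted p-values of these 12 genes were 1.83e-26 or less. In all, 11842 genes changed, 5920 higher and 5922 lower, with 1486 and 1032 by at least 2-fold. SOX10 changed 9205 genes in guide 1 and 10229 in guide 2, of which 7689 moved the same way and 21 in opposite directions (r = 0.887 across genes), where independent lists would share 1138 upward and 1097 downward.

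SOX10 lineage genes rose with SOX10 in knockout cells and interferon genes fell. Of 29 lineage genes 21 rose and 5 fell, with CDH19 at 3.82, ERBB3 at 2.66 and RXRG at 6.42 (adjusted p = 2.84e-06, and 0.00817 with an estimated correlation). Of 37 interferon genes 28 fell and 3 rose, with OASL at −2.86, IFI44 at −1.11 and BST2 at −2.38 (7.62e-06, and adjusted p = 0.298 with an estimated correlation). Antigen presentation rose in 15 of 25 genes and fell in 8, with CD74 at 1.53, HLA-DRA at 1.61 and CIITA at 2.13 (0.00131, and adjusted p = 0.251 with an estimated correlation). Pigmentation genes rose in 12 of 21 cases and fell in 5 (DCT 7.48, ST3GAL6 1.40; 0.0269, and adjusted p = 0.134 with an estimated correlation), and this call did not hold with only the compared groups in the fit (0.0789). Undifferentiated-state genes fell in 19 of 30 and rose in 11, with IGFBP3 at 2.01 among the latter (0.0261, and adjusted p = 0.292 with an estimated correlation), and did not pass with a filter at a mean CPM of 1 (0.0576). S phase genes rose in 18 of 26 and fell in 1 (0.00131, and adjusted p = 0.396 with an estimated correlation), whereas G2 and M genes fell in 22 of 26 and rose in 1 (AURKA −0.36; 1.01e-05, and 0.0113 with an estimated correlation). MYC targets fell in 26 of 30 and rose in 1 (ODC1 −1.05; 1.07e-05, and adjusted p = 0.292 with an estimated correlation). Members that changed adjusted over the list alone numbered 26, 32, 23, 17, 30, 19, 24 and 27. Of the fibroblast markers, 7 of 10 fell and 2 rose (adjusted p = 0.173).

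To ask whether SOX10 turned back the knockout profile, genes were chosen with 1 guide and the SOX10 effect was read with the other. Of the 11086 genes changed by guide 1, 65.0% had a SOX10 effect of opposite sign in guide 2 (95% exact interval 64.1 to 65.9), and 44.8% were changed in the opposite direction against 18.2% in the same. Of the 11775 genes changed by guide 2, 69.2% had a SOX10 effect of opposite sign in guide 1 (68.3 to 70.0). Simulated data with no effect gave 50.2% for guide 1 with SOX10 in guide 2, over all 19403 genes rather than over genes chosen as changed. The share was larger among genes that the knockout moved at least 2-fold. With genes chosen in guide 1, the SOX10 effect had the opposite sign for 89.8% of the 921 that fell and 74.0% of the 1953 that rose. It passed the threshold in the opposite direction for 72.6% and 50.4% and in the same direction for 4.23% and 11.1%, and its median was 79.5% and 30.8% of the knockout change on the log2 scale, with the opposite sign. With genes chosen in guide 2 the sign was opposite for 86.8% and 75.5%, the threshold was passed in the opposite direction for 67.9% and 52.0% and in the same for 5.36% and 10.0%, and the medians were 51.3% and 32.1%. Across all genes the log2 changes of knockout in one guide and SOX10 in the other correlated at r = −0.484 and −0.498.

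**Figure D4:**
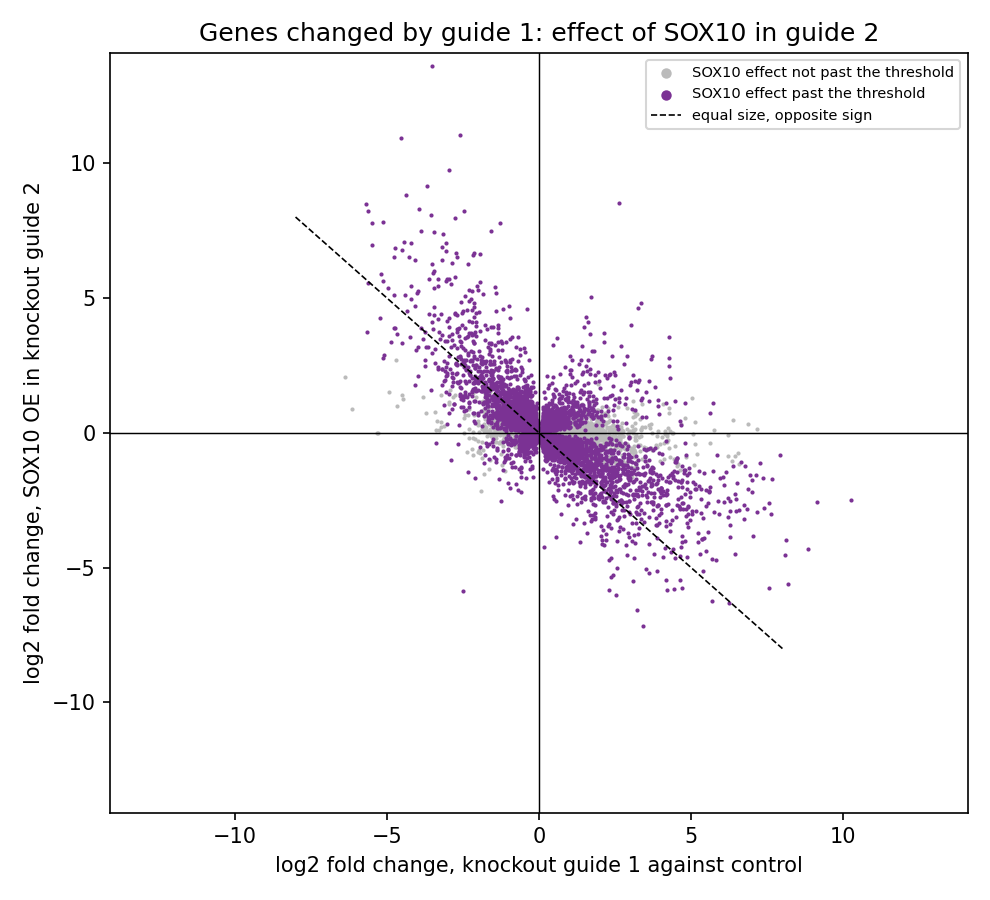
Log2 fold change with guide 1 against control (horizontal axis) and with SOX10 in guide 2 (vertical axis) for the 11086 genes changed by guide 1, 1 point per gene. Purple points passed the threshold for SOX10 and grey points did not; the dashed line marks equal size with opposite sign, and 65.0% of the genes have opposite signs.

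Knockout cells with SOX10 still differed from control cells at many genes. Of the 1753 genes that both guides raised at least 2-fold, SOX10 lowered 882 (50.3%) in both, and 865 (49.3%) stayed at least 2-fold above control. Of the 827 that both guides lowered, SOX10 raised 602 (72.8%), and 185 (22.4%) stayed at least 2-fold below. Unlike the shares read across guides, these counts use the same knockout libraries for the choice and for the SOX10 effect, which favours opposite signs. The same control libraries likewise entered the choice and the distance that remained. Against control, 12192 genes changed, 6326 higher and 5866 lower, with 2088 and 576 by at least 2-fold. Library-size scaling gave 9156 and 3295, or 73.5% against 51.9% higher, with a median shift of 0.147. MOBP, PMP2 and TRIM48 were far above control at the levels given, as were CNTN6 (6.57 and 5.33 CPM against 0.0253 CPM) and SLC18A1 (21.2 and 20.9 CPM against 0.278 CPM). SOX10 alone also raised all of these in control cells, CNTN6 to 6.46 CPM and SLC18A1 to 13.7 CPM. MMP12, the macrophage elastase gene, was 189-fold higher at 22.5 ± 0.392 and 27.6 ± 1.27 CPM against 0.131 ± 0.0853 CPM. SOX10 alone brought MMP12 to 2.63 CPM in control cells. IL1RL1 was 23.2-fold lower, the hyaluronidase gene CEMIP 13.0-fold, the secreted kinase gene FAM20C 12.6-fold, PKNOX2 12.6-fold, the neural crest factor gene TFAP2B 11.3-fold and the ion exchanger gene SLC24A3 10.4-fold. CEMIP was at 230 ± 3.67 CPM in control cells and at 30.1 ± 3.88 and 10.2 ± 1.95 CPM (adjusted p = 1.53e-12, the weakest of the 12). IL1RL1 was at 0.853 CPM with SOX10 alone, and at 31.0 and 23.3 CPM with the knockout alone, against 27.7 CPM in control cells. Differences from control in this comparison therefore include effects of SOX10 alone.

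Pigmentation genes stood above control in these cells and G2 and M genes below. Of 21 pigmentation genes 15 were higher and 3 lower, or 15 and 0 with library-size scaling, with DCT at 3.60, GPNMB at 0.90 and RAB27A at 1.22 (adjusted p = 0.00107, and 0.0222 with an estimated correlation). SOX10 lineage genes were lower in 13 of 29 and higher in 9 (ERBB3 −1.44, SOX2 −1.61; adjusted p = 0.11), but 12 were lower and 13 higher with library-size scaling, and the median of 0.02 differed in sign from the mean of −0.22 and the test. All 26 G2 and M genes were lower, or 23 lower and 1 higher with library-size scaling, with KIF20A at −0.83 and PLK1 at −0.73 (8.78e-13, and 0.000448 with an estimated correlation). MYC targets were lower in 27 of 30 and higher in 0, or 21 and 2 with library-size scaling (HSPD1 −0.51; 1.19e-09, and adjusted p = 0.139 with an estimated correlation). S phase genes were lower in 18 of 26 and higher in 2, but in 9 and 9 with library-size scaling, which ended the call (0.00132 against 0.0547, and adjusted p = 0.296 with an estimated correlation). Interferon genes were higher in 29 of 37 and lower in 3 (GBP1 1.78, IFI6 1.85; 1.6e-05, and adjusted p = 0.206 with an estimated correlation). YAP and TEAD targets were higher in 16 of 24 and lower in 5, or 19 and 3 with library-size scaling (IGFBP3 0.99; 0.000658, and adjusted p = 0.206 with an estimated correlation). MAPK outputs were lower in 15 of 25 and higher in 9 (DUSP4 −1.79; 0.00344, and adjusted p = 0.117 with an estimated correlation), and antigen presentation in 14 and 6 of 25 (CIITA −1.29; 0.00442, and adjusted p = 0.206 with an estimated correlation). Fibroblast markers were higher in 6 of 10 and lower in 1, with LUM at 3.94 and DCN at 1.92, and epithelial markers in 6 and 1 of 11, with DSP at 2.32 (0.00344 and 0.0129, and adjusted p = 0.139 for both with an estimated correlation). With library-size scaling 8 and 6 of these markers were higher and 0 lower. Mitochondrially encoded transcripts were higher in 7 of 13, or 12 with library-size scaling (MT-CO2 0.57; adjusted p = 0.0624). Adjusted over the list alone, 19, 22, 26, 28, 21, 32, 21, 25, 20, 7, 8 and 7 members changed.

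Within SOX10-overexpressing cells, inflammatory genes were still higher and SOX10 lineage genes lower with the knockout. Counted SOX10 was 452 CPM in control cells with SOX10, against 291 and 246 CPM in the knockout lines with SOX10. The knockout and the lower SOX10 level therefore cannot be told apart in this contrast. Of 11579 changed genes 5946 were higher and 5633 lower, or 9144 and 3126 with library-size scaling (74.5% against 51.4% higher). Of 22 NF-kB genes 17 rose and 1 fell, with IL11 at 2.01 and BIRC3 at 1.40 (adjusted p = 3.26e-06, and 0.00218 with an estimated correlation). Hypoxia and glycolysis genes fell in 20 of 25 and rose in 2, with LDHA at −0.85 and BNIP3 at −0.90 (5.67e-09, and 0.011 with an estimated correlation). SOX10 lineage genes fell in 19 of 29 and rose in 5, with RXRG at −2.23 (3.85e-05, and 0.011 with an estimated correlation), and antigen presentation fell in 17 of 25 and rose in 5, with CIITA at −2.15 (2.24e-06, and 0.0399 with an estimated correlation). Adjusted over the list alone, 19, 22, 25 and 23 members changed. The knockout effects without and with SOX10 correlated at r = 0.703 across genes, with a slope of 0.61; 7995 genes changed the same way and 796 in opposite ways.

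The SOX10 effect itself differed between knockout and control cells, which the interaction tested directly. The counted SOX10 transcript rose by a log2 of 0.35 in control cells and 2.15 in knockout cells, from a lowered level in the latter. Background and size of the SOX10 rise therefore cannot be told apart in this contrast. The interaction passed for 7005 genes, 3818 with a more positive and 3187 with a more negative SOX10 effect in knockout cells, and for 829 and 425 by at least 2-fold. SOX10 changed 4648 genes the same way in both backgrounds and 929 in opposite ways, 388 of them higher in control and lower in knockout cells and 541 the reverse. KDR, the VEGF receptor gene, went from 3.26 to 10.5 CPM in control cells, but from 0.395 and 0.254 to 27.7 and 33.1 CPM in guides 1 and 2, an interaction of 4.90 on the log2 scale (SE 0.134, adjusted p = 1e-28). FAT3 had an interaction of 4.41, and SLC18A1 and MUC7 had 6.05 and 5.58, where fitted folds depend on the prior count because of near-zero levels in knockout cells. RELN, a secreted matrix protein gene, went from 0.160 to 0.243 CPM in control cells and from 6.70 and 8.48 to 0.549 and 0.539 CPM in knockout cells (−4.36). MMP3 (−3.33), the protocadherin gene PCDH7 (−2.57) and GDF15 (−2.45) followed. PCDH7 rose in control cells with SOX10, from 8.88 to 33.6 CPM, and went from 5.59 and 4.47 to 5.74 and 1.77 CPM in knockout cells. MITF, among the members of the pigmentation list with the lowest interaction p, rose with SOX10 in control cells and fell with it in knockout cells, from 84.3 and 92.1 to 64.2 and 56.3 CPM (interaction −1.66).

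Among gene lists, SOX10 lineage, S phase and receptor kinase genes had a more positive SOX10 effect in knockout cells, and p53 and interferon genes a more negative one. Lineage genes passed upward in 18 of 29 and downward in 7, with CDH19 at 3.29 and NGFR at 2.30 (adjusted p = 7.97e-06, and 0.0156 with an estimated correlation). S phase genes passed upward in 23 of 26 and downward in 0, with UHRF1 at 0.60 (3.58e-13, and adjusted p = 0.0654 with an estimated correlation). Receptor tyrosine kinases passed upward in 15 of 22 and downward in 2 (9.09e-06, and adjusted p = 0.0538 with an estimated correlation). Of 22 p53 targets 10 passed downward and 1 upward, or 13 and 1 with library-size scaling, with ZMAT3 at −0.42 (4.68e-05, and 0.0349 with an estimated correlation). Interferon genes passed downward in 20 of 37 and upward in 2, with IFITM1 at −3.89 and BST2 at −2.62 (1.53e-08, and adjusted p = 0.106 with an estimated correlation). The members past the threshold adjusted over the list alone numbered 27, 23, 17, 13 and 24.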

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

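Chosen only after the result was seen were the tests of an off-target edit, of uncounted transgene reads, of reads from glial cells and of reads from fibroblasts; the test of a SOX10 shortage was set before. The bounds of the scaling tests were written before their values were seen, but library-size scaling itself was chosen after seeing the data. The bounds of the glial and fibroblast tests were also rewritten after the values were seen, and their first wording, which asked every marker at once, had left both undecided. The interactions and the differences between guides stood out in a direct test of the difference; the patterns of the last 3 paragraphs came from comparisons with control cells and not from such a test.

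The SOX10 effect differed between knockout and control cells for 7005 genes, and for 929 of them SOX10 acted in opposite directions. The counted SOX10 rise was itself larger in knockout cells, so background and size of the rise cannot be told apart here. Of the 51 named genes examined, 29 had an interaction of at least 2-fold, 6 had a smaller one past the threshold and 16 did not pass. Most of them were chosen from these data for large changes, some for the interaction itself, so this share tests nothing. Of all 21060 genes, 1254 had an interaction of at least 2-fold. Some genes that the knockout lowered were raised by SOX10 with a larger fold in knockout cells. They included KDR (4.90 on the log2 scale), FAT3 (4.41), ITIH5 (4.02), the collagenase gene MMP8 (3.98), RXRG (3.27), GAS7 (2.92) and PKNOX2 (2.36). PTPRZ1 (1.87) and SOX10 itself (1.80) did so too. These folds start from lowered levels. With SOX10, all of them but KDR stayed lower in both knockout lines than in control cells. RXRG reached 19.8 and 12.7 CPM against 74.3 CPM, and KDR 27.7 and 33.1 CPM against 10.5 CPM. Higher interactions were also found for SLC18A1 (6.05), MUC7 (5.58), COL14A1 (4.26) and PMP2 (2.73), whose levels in knockout cells were so low that these fitted values depend on the prior count. KRTAP2-3 (2.11), MGAM2 (1.70), SHISA2 (1.44), SLC24A3 (1.25), SMOC1 (1.20), TNFRSF19 (1.16) and ANKRD1 (1.16) followed. More negative SOX10 effects in knockout cells were found for RELN (−4.36), MMP3 (−3.33), SLC5A4 (−2.80), SHOC1 (−2.62), PCDH7 (−2.57), GDF15 (−2.45), MMP1 (−2.28), CDH11 (−1.37) and STC1 (−1.04). Among these, SLC5A4 stood at 0.0151, 0.0306 and 0.0597 CPM in control cells and guides 1 and 2 without SOX10, and SHOC1 at 0.0552 and 0.0231 CPM in control cells without and with SOX10, levels near a count of 3 per library, so their interactions are uncertain and depend on the prior count (adjusted p = 0.00183 and 0.0479). Among gene lists whose test held with an estimated correlation, 25 SOX10 lineage genes and 11 p53 targets had an interaction.

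The guides differed at 1841 genes, and the SOX10 effect differed between them at 528. Members that differed between guides numbered 15 in the SOX10 lineage list, 16 in the undifferentiated-state list, 16 among MAPK outputs, 6 among receptor tyrosine kinases, 10 in the TGF-beta list, 17 among matrix genes, 15 among integrins, 15 in antigen presentation, 8 among G2 and M genes and 11 among lysosome genes.

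Knockout cells with SOX10 stayed at least 2-fold from control in both lines at 2024 genes, 1659 higher and 365 lower. If a remaining shortage of SOX10 were the cause of all of them, they would lie nearer control with SOX10 than without it, but of genes chosen in 1 guide at most 38.5% had a SOX10 effect towards control in the other, by sign and with no threshold. This argues against a shortage as the cause of the whole set only. The choice of genes by their level with SOX10 takes in genes that SOX10 itself moved away and lowers the share: 1050 of the 2024 were already 2-fold away on that side without SOX10. Among genes 2-fold away in both states, 57.6% of 1192 chosen in guide 1 and 63.1% of 1594 chosen in guide 2 had that sign, so for these a shortage stays open. With library-size scaling 96% of the genes stayed 2-fold away on the same side. That scaling moves the median of all genes by only 0.147 on the log2 scale. The choice between the 2 scalings thus matters little for genes this far from control. Both scalings are relative, so a change in total RNA per cell was not tested. At least 84.9% of the genes 2-fold away with 1 guide changed the same way with the other, but both lines were measured against the same control libraries. Both lines also overexpressed SOX10, so effects of SOX10 are shared whatever the guides cut, and this share cannot decide on an off-target edit. In 20 simulations of unchanged groups against those controls, a mean of 0.05 genes changed the same way in both. With the other guide measured against SOX10-overexpressing control cells, so that no library was shared, 68.2% and 65.9% changed the same way, where 28% and 23.7% were expected at random. The shares of 68.2% and 65.9% argue against an off-target edit of a single guide as the cause of most of the set, and for the rest it stays open. A candidate explanation is an effect of the TADA2B knockout that does not run through SOX10, perhaps joined by effects of SOX10 itself. SOX10 changed 894 of the 2024 genes the same way in control cells, and 34.4% of all genes in either direction. That comparison shares the control libraries by which the genes were chosen. The number expected from this sharing was not computed, so the 894 genes are not a test.

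SLC5A4, CNTN6, PMP2, TRIM48, MOBP and DCT rose over 100-fold in control cells with SOX10 although the counted SOX10 rose only 1.28-fold. All 6 were also above control in both knockout lines with SOX10, where counted SOX10 was below control, so transgene reads not counted at the SOX10 gene may hide part of its level. That stays open, because the transgene sequence is not given in the sources used here. Reads from glial cells would bring the abundant myelin transcript MBP, which stood at 0.184% of the PMP2 level. This test took the lowest of several markers, the others did not lie below its bound, and it therefore rests on MBP alone. No measurement of SOX10 protein was analysed here.

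Fibroblast markers were higher in knockout cells, LUM and COL1A1 among them. Fibroblasts bring all of their abundant collagen transcripts, but COL1A2 was at most 0.514% of the COL1A1 level, at 0.0403 and 0.0468 CPM in the knockout lines, which argues against reads from such cells. COL3A1 was at 0.257 and 0.357 CPM and DCN at 0.819 and 0.712 CPM, and COL1A2, COL3A1 and DCN were chosen here after their values were seen. With library-size scaling 88.9% of the changed markers kept their call and direction. That scaling moves the median of all genes by only 0.155 on the log2 scale, so the choice between the 2 scalings matters little for them. A change in total RNA per cell was not tested. Expression of these genes by the knockout cells themselves is a candidate explanation found and tested on the same libraries.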

How the results depend on the processing

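Library-size scaling without TMM was the only alternative chosen after seeing the data; all others were set before. The 25 counts and shares had 419 alternative values, of which 403 stayed within 1.5 times the count or within the interval of the share. Of 6033 alternative values for 329 results of single genes, 6021 kept their direction and side of the threshold, and of 1131 values for 68 gene list results 1094 did. Gene lists were not run with limma-voom or DESeq2. The 68 were lists that passed in the main fit, so lists that did not pass were not followed. List tests of guide 2 against guide 1 and of knockout within SOX10-overexpressing cells were not repeated under any alternative. For these contrasts only the counts of members were taken with library-size scaling.

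A filter at a mean CPM of 1 tests fewer genes by construction and lowered the counts of genes changed at least 2-fold. They became 1444 for the knockout, 1320 and 1571 for guides 1 and 2, 634 for SOX10 in control cells, 976 for SOX10 in knockout cells, 978 and 1044 for SOX10 in guides 1 and 2, 1118 for knockout with SOX10 against control, 1102 for knockout within SOX10-overexpressing cells, 585 for the interaction and 87 between the guides. The share of genes with opposite SOX10 effect moved with this filter to 63.7% for genes chosen in guide 1 and 67.9% for guide 2, and to 66.4% for guide 1 with library-size scaling and 70.4% for guide 2 without a low-count filter. Leaving out each library in turn gave 68.4% to 70.1% for guide 2, the highest without guide 2 replicate 2. Beyond the number of genes tested, the cause was not tested.

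Leaving out each library in turn gave 11381 to 12264 genes changed by the knockout, 9358 to 9887 changed the same way by both guides, 6335 to 6559 changed by SOX10 in control cells, 6215 to 7272 with an interaction and 1340 to 1833 between the guides. In these fits the spread was taken from all groups together.

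Among results of single genes, the only change of direction was for POLE3 in knockout cells with SOX10 against control, a log2 change of −0.10 that became 0.047 with library-size scaling (adjusted p = 0.108); that scaling shifts all genes upward by construction. Members of gene lists that are not reported singly also changed direction with it, in the knockout 2 each in the G2 and M, lysosome and oxidative phosphorylation lists and 1 each in the cholesterol and ATAC lists. List medians changed sign as well, such as those of MYC targets (−0.14 to 0.01) and ATAC subunits (−0.12 to 0.03) in the knockout. POLE4 lost its call there with that scaling (0.0673). TADA2B, which did not pass with SOX10 in knockout cells, passed in 5 alternatives with adjusted p-values of 0.0272 to 0.0476: RLE, library-size scaling, DESeq2, and without guide 1 with SOX10 replicate 2 or guide 2 replicate 2. With SOX10 in control cells, ITGAM did not pass without SOX10 replicate 1 (0.0615), and CD14 did not pass without control replicate 1 or 3 or SOX10 replicate 1 or 2 (0.0545 to 0.075). These leukocyte genes stood at only 0.0906 and 0.296 CPM in control cells. The cause was not tested for these.

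Gene list calls ended in 20 cases on leaving out a library, in 7 with the filter at a mean CPM of 1, in 5 with library-size scaling, in 4 with only the compared groups in the fit and in 1 with the replicate block. Each is given beside its list. The cause was not tested.

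The replicate numbers were related to the samples in some pairs of groups and not in others. Deviations of same-numbered libraries from their group means correlated at −0.192 to 0.338, above 0.1 in 16 of 45 pairs, with a mean of 0.055 against −0.028 for different numbers, and 11 of 18 libraries correlated best with a library of their own number. All same-numbered pairs of control with guide 1 (0.124 to 0.153) and of guide 1 with guide 2 (0.109 to 0.234) lay above 0.1, so a link by number between those groups stays open. With the replicate number as a block, 12322 genes changed by the knockout and 10073 the same way by both guides, 2036 differed between guides, and the shares with opposite SOX10 effect were 64.9% and 69.1%. The block ended only the NF-kB call of the interaction (adjusted p = 0.0571).

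At these depths a count of 3 corresponds to 0.0376 to 0.0512 CPM, so differences among genes below that level were not detectable.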

Other observations

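In this part only library-size scaling was chosen after the result was seen. Heat shock and stress response genes were lower in knockout cells, and the cholesterol, lysosome and oxidative phosphorylation lists did not pass. Of 14 heat shock genes 10 fell and 1 rose, or 7 and 2 with library-size scaling, with HSP90AA1 at −0.88, HSP90AB1 at −0.52 and HSPA4L at 0.73 (adjusted p = 0.0024, and adjusted p = 0.216 with an estimated correlation). The unfolded protein and stress response list fell in 15 of 24 genes and rose in 6, or 11 and 9 with library-size scaling, with DDIT4 at −2.08 and HSP90B1 at −0.51. Its adjusted p of 0.0312 became adjusted p = 0.313 with an estimated correlation, and the call ended with a filter at a mean CPM of 1 (0.0663), library-size scaling (0.0523), only the compared groups (0.0504) and without control replicate 3 (0.0519). Cholesterol genes fell in 7 of 23 and rose in 5, or 4 and 14 with library-size scaling, with STARD4 at 0.95 among those that rose (adjusted p = 0.825). Lysosome genes fell in 11 of 25 and rose in 9, or 4 and 15 with library-size scaling, with CTSF at −0.79 (0.803). Nuclear-encoded oxidative phosphorylation genes rose in 7 of 23 and fell in 4, or 20 and 0 with library-size scaling, and their regulator PPARGC1A rose by 3.22 (0.546). Subunits of ATAC, a complex related to SAGA, fell in 6 of 9 cases and rose in 0, or 1 and 4 with library-size scaling, with YEATS2 at −0.29 (0.0848). Changed members adjusted over the list alone numbered 12, 21, 12, 20, 11 and 6.

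Markers of immune and endothelial cells included genes that moved far. LAPTM5, a lysosomal membrane protein gene of leukocytes, rose from 1.77 to 13.5 CPM in knockout cells, and CSF1R from 0.121 to 0.985 CPM. Of 8 endothelial markers 2 rose and 3 fell in the knockout, or 3 and 2 with library-size scaling, with CDH5 at 1.65 and ESAM at −1.14, a median of 0.29 and a mean of −0.30 (adjusted p = 0.95, 5 changed adjusted over the list alone). In control cells with SOX10, LAPTM5 had a log2 change of −2.81, and 4 of 9 leukocyte markers fell and 0 rose, 4 of them adjusted over the list alone. The adjusted p of 0.0467 became adjusted p = 0.155 with an estimated correlation, and the call ended without control replicate 2 (0.0557), control replicate 3 (0.0629) or SOX10 replicate 2 (0.0563).

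With SOX10 in control cells, p53 targets rose in 13 of 22 cases and fell in 0, with ZMAT3 at 0.66 and TP53I3 at 0.46 (adjusted p = 0.00189, and 0.0412 with an estimated correlation). Stress response genes rose in 13 of 24 and fell in 5 (HSP90B1 0.22; 0.0148, and adjusted p = 0.251 with an estimated correlation), and MYC targets fell in 16 of 30 and rose in 1 (NOP56 −0.13; 0.00398, and adjusted p = 0.351 with an estimated correlation). Receptor tyrosine kinase genes fell in 11 of 22 and rose in 6, with MET at −0.95 and AXL at −0.45, and the mean of 0.04 differed in sign from the median of −0.12 and the test. Their adjusted p was 0.0356, and adjusted p = 0.235 with an estimated correlation, and the call ended with only the compared groups in the fit (0.0563). In these lists 13, 19, 18 and 17 members changed adjusted over the list alone. In knockout cells with SOX10, oxidative phosphorylation genes fell in 17 of 23 and rose in 3 (SDHB −0.23; 0.00236, and adjusted p = 0.292 with an estimated correlation), with 21 changed adjusted over the list alone.

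Against control, knockout cells with SOX10 had lower heat shock genes in 10 of 14 cases and higher in 2 (HSP90AA1 −0.82; adjusted p = 0.00265), lower hypoxia genes in 14 of 25 and higher in 5, or 13 and 10 with library-size scaling (LDHA −0.63; 0.00626), and lower matrix genes in 19 of 34 and higher in 12 (SPARC −0.86; 0.0181). With an estimated correlation these gave adjusted p = 0.206, 0.206 and 0.314. ATAC subunits were lower in 5 of 9 and higher in 0, or 2 and 2 with library-size scaling, with DR1 at −0.26 (0.0474, and adjusted p = 0.139 with an estimated correlation). Their call ended with library-size scaling (0.444), with a filter at a mean CPM of 1 (0.162), and without control replicate 2 (0.0628), guide 1 with SOX10 replicate 1 (0.0538) or guide 2 with SOX10 replicate 2 (0.052). Changed members adjusted over the list alone numbered 12, 19, 31 and 5. Within SOX10-overexpressing cells, the knockout lowered 25 of 26 G2 and M genes and raised 0, or 19 and 2 with library-size scaling (KIF20A −0.64; 7.72e-10, and 0.00156 with an estimated correlation), and raised 8 of 11 epithelial markers and lowered 1, or 8 and 0 with library-size scaling (KRT8 2.68; 0.000377, and 0.0279 with an estimated correlation). YAP targets rose in 17 of 24 and fell in 2, or 20 and 1 with library-size scaling (IGFBP3 1.65; 2.24e-06, and adjusted p = 0.123 with an estimated correlation). Here 25, 9 and 19 members changed adjusted over the list alone. Counted SOX10 was lower in these knockout lines than in control cells with SOX10, so its level and the knockout cannot be told apart.

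For the interaction, YAP targets passed upward in 16 of 24 and downward in 3, or 13 and 3 with library-size scaling (IGFBP3 2.67), integrins in 16 and 6 of 26 (CADM1 1.19), hypoxia genes downward in 15 of 25 and upward in 2 (ADM −1.21), and oxidative phosphorylation genes downward in 11 of 23 and upward in 1, or 14 and 1 with library-size scaling (COX5B −0.38). Lysosome genes passed downward in 12 of 25 and upward in 4 (CTSL −0.55), and MYC targets downward in 12 of 30 and upward in 2 (ODC1 −0.48). The adjusted p-values were 0.000199, 0.0056, 0.000202, 0.000199, 0.00748 and 0.015, and adjusted p = 0.168, 0.106, 0.106, 0.106, 0.106 and 0.435 with an estimated correlation. Fibroblast markers passed downward in 4 of 10 and upward in 1 (FAP −3.70; adjusted p = 0.00748, and adjusted p = 0.106 with an estimated correlation), which ended with a filter at a mean CPM of 1 (0.161). AP-1 genes passed upward in 10 of 19 and downward in 3 (NR4A1 1.80; 0.0406, and adjusted p = 0.106 with an estimated correlation), which ended with that filter (0.139) and without guide 2 replicate 2 (0.0541). NF-kB genes passed upward in 12 of 22 and downward in 5 (IL1A 2.25; 0.0474, and adjusted p = 0.106 with an estimated correlation), which ended with that filter (0.293), with the replicate block (0.0571) and without control replicate 1 or 3, SOX10 replicate 2, guide 1 replicate 3 or guide 2 with SOX10 replicate 3 (0.0517 to 0.0582). In the order given, 20, 22, 19, 15, 17, 14, 5, 15 and 20 members passed adjusted over the list alone.

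Compared with guide 1, guide 2 had lower matrix genes in 15 of 34 cases and higher in 2 (TIMP3 −1.10), lower lysosome genes in 11 of 25 and higher in 0 (SQSTM1 −0.26), lower G2 and M genes in 8 of 26 and higher in 0 (KIF20A −0.19), and lower undifferentiated-state genes in 13 of 30 and higher in 3 (SPARC −0.54). Receptor tyrosine kinases were lower in 5 of 22 and higher in 1 (DDR1 −0.53), and TGF-beta genes lower in 8 of 24 and higher in 2 (TNC −0.43). Their adjusted p-values were 5.62e-09, 1.83e-08, 1.17e-05, 0.000632, 0.000119 and 0.00686, and with an estimated correlation 0.0271, 0.00339, 0.00517, 0.0492, 0.0472 and 0.0271. YAP targets were higher in 10 of 24 and lower in 4 (CCN1 0.48; 8.29e-05), interferon genes higher in 4 of 37 and lower in 0 (GBP1 0.36; 0.000942), and MYC targets higher in 6 of 30 and lower in 1, or 12 and 1 with library-size scaling (ODC1 0.16; 4.05e-05), with adjusted p = 0.19, 0.408 and 0.229 with an estimated correlation. Hypoxia genes were lower in 7 of 25 and higher in 3 (PKM −0.17; 0.0228, and adjusted p = 0.26 with an estimated correlation). Adjusted over the list alone, 19, 13, 11, 18, 11, 11, 16, 5, 13 and 11 members differed.

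The SOX10 effects in control and knockout cells correlated at r = 0.621 across genes, which are not independent replicates. Of the 4648 genes changed the same way, 1962 had an interaction, with a larger SOX10 effect in knockout cells for 1253 and a smaller one for 709. A further 2870 genes changed in knockout cells alone and 1073 in control cells alone, each with an interaction.

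Other splits of the same libraries into groups of the same sizes were fitted with only those groups. For each of the following, 1 of 50 splits, the real one, gave as many genes, a share under 0.05. This concerns only how the libraries were grouped. Splits that mix unlike groups raise the fitted spread, which favours the real split. The libraries of a group may also be technical repeats, so a chance difference between the cell lines was not excluded. The real value and the highest of the other splits were 11800 and 11259 for the knockout, 9654 and 9220 for genes changed the same way by both guides, 12074 and 11193 for knockout with SOX10 against control, 11512 and 6050 for knockout within SOX10-overexpressing cells, 11662 and 2 for SOX10 in knockout cells, and 7005 and 4101 for the interaction. The highest others of the first 3 came from the 1 drawn split that kept the control libraries together and exchanged libraries only between guides. Among splits that mixed control and knockout libraries the highest were 6822, 5 and 5734. For single groups of 3 against 3, 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many genes each time. The real and highest other values were 11027 and 0 for guide 1, 10917 and 0 for guide 2, 7378 and 0 for SOX10 in control cells, 9249 and 0 for SOX10 in guide 1, 9469 and 4 for SOX10 in guide 2, and 1459 and 0 for guide 2 against guide 1.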
